A study of Homo sapiens with 4 samples.

How the data were processed

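RNA was measured by poly(A) RNA sequencing in 4 libraries of H1299 cells, 2 expressing p53WT and 2 expressing CASM34. Per the labels' protocols, the cells were grown in RPMI medium with serum, and total RNA was isolated on columns, checked on a Bioanalyzer and purified for poly(A) RNA. Per the submitters' processing notes, Trim Galore, STAR, RSEM and the genome build GRCh38 were used. Their versions, the annotation release and the strand setting are not given in the sources used here. The deposited tables hold, per the file headers, the RSEM expected count, effective length, TPM and FPKM of 61852 genes in each library. The expected counts are estimated by the authors' RSEM run, which shares reads that match several gene models among them, so 8.63% to 9.26% of genes per library had a count that was not whole (tolerance 0.001). The deposited TPM values are named so per the file headers, a unit that divides counts by effective length and scales them to a fixed total per library. FPKM was not used here.

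The groups follow the labels. Gene names were matched by gene ID for 61803 of the 61852 IDs, 59984 of them with the same version, and coordinates are those of GENCODE 29 on GRCh38, 1-based. The expected counts were rounded to whole numbers, and the totals per library were 21717726 and 25969760 (p53WT) and 26906095 and 18086983 (CASM34). A floor of 3 counts per library, equal to 0.138 CPM in the shallower p53WT library, stands for a count of 0, and it covers counting error only. Counts of the same gene differed between the 2 libraries of a group by more than Poisson counting error, with chi-square per degree of freedom of 3.89 in p53WT and 3.94 in CASM34, so neither group holds a duplicated library. No sample was left out.

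The groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, group as the only term). Of the 61852 genes 15965 were tested and 45887 were removed as too low. Fold changes are CASM34 over p53WT on the log2 scale, standard errors are the absolute log2 fold change divided by the square root of F, and a gene is said to rise or fall at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The common dispersion was 0.00193, a coefficient of variation of 0.0440. CPM values use the TMM factors, which lay between 0.993 and 1.01.

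Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. An estimated correlation and fry were run beside it, and p-values were adjusted over the 20 lists with at least 3 tested members. There were 22 lists, of which 4 held p53 targets (57 genes). Others held p53-DREAM repressed cell cycle genes, S phase and E2F genes, DNA damage sensing and repair, and the unfolded protein and integrated stress response. Further lists covered heat shock, interferon, NF-kB, immediate early genes, epithelial-mesenchymal and matrix genes, hypoxia and glycolysis, cholesterol synthesis, NRF2 and ribosomal proteins. The last were mitochondrially encoded mRNAs, RNAs taken to lack a poly(A) tail, and markers of leukocytes, of fibroblasts and endothelium and of epithelial lines. The groups, the tests, the lists, the rule for named genes and all alternatives except the GC and length offset were chosen before the data were examined. The rule named 7 p53 targets, the 12 largest rises and 12 largest falls among genes with a symbol that passed, had a mean of at least 1 CPM and had groups that did not overlap, and up to 4 passing members of each list by adjusted p. It named 47 genes, of which 44 passed, besides some that are not reported here.

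The alternatives were median-of-ratios, upper-quartile and library-total scaling, no filter on low counts (any gene with at least 1 count), a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), an offset for effective length, a replicate block, leaving out the mitochondrially encoded genes, leaving out each library in turn, a threshold of 1.5-fold (glmTreat) and an adjusted p under 0.01. The GC and length offset was added after the data were seen: for each library, the deviation of log2 CPM from the gene's mean was fitted with natural splines (5 degrees of freedom each) on transcript GC content and effective length, and the fit entered edgeR as an offset. It was also used for camera. Random lists matched to the p53 targets were drawn from the 100 nearest genes in GC content and mean expression, 10000 times.

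The scripts were tested on simulated data before use, with counts drawn for the 15965 genes from the means and library sizes of these libraries and 50 genes changed at each of 4 fold sizes. The edgeR test recovered 40% of 50 genes changed 1.25-fold, 70% at 1.5-fold, 88% at 2-fold and 96% at 4-fold, and 16 of its 163 calls were false (9.82%). With no gene changed it made 6 calls. With the fitted GC and length trend as the only difference it made 323 calls, and 1 with the offset. With the changed genes and that trend together it made 642 calls, 482 of them false (75.1%). The offset brought this to 166 calls, 16 of them false (9.64%). The simulated trend was the one the offset itself had fitted, and the changed genes were drawn without regard to GC content. These runs therefore cannot show whether the offset also removes a real change linked to GC content. In the list simulation, 10 lists of 20 genes were shifted by 0.15 on the log2 scale and 20 lists were left unshifted. Camera with the preset correlation passed 10 and 0, fry passed 2 and 0, and camera with an estimated correlation passed 0 and 0. At this design an estimated correlation thus detected no shift of this size. The simulated genes were drawn independently, so these results cannot show that the preset correlation holds for the real lists. Estimated correlations of the real lists ran from -0.334 (epithelial line markers) to 0.803 (ribosomal proteins). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.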

Results

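RNA was sequenced from 4 libraries of H1299, an established human non-small-cell lung carcinoma line that lacks endogenous p53. In 2 libraries the cells expressed wild-type p53 (p53WT) and in 2 they expressed CASM34. The title of the series names synonymous mutations found in cancer and the response of p53 to DNA damage, so the comparison asks how the transcriptome differs between cells with CASM34 and cells with p53WT. The labels state no treatment, and no library of cells without p53 was analysed here, so p53WT is the reference throughout. The estimated counts totalled 21717726 and 25969760 in the p53WT libraries and 26906095 and 18086983 in the CASM34 libraries, with at least 1 count for 21595 to 22504 genes. Nothing in the labels says that the 2 libraries of a group come from separate cultures. Every p-value below for a single gene thus measures only the spread between these libraries, which may be technical. Camera with its preset correlation sets a list against the spread between genes, and Fisher's test counts genes. Genes are not independent replicates, so those p-values do not measure how far new libraries would differ.

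Several direct p53 target genes were higher in cells with CASM34 than in cells with p53WT. Among them were the cell cycle inhibitor CDKN1A, the p53 ubiquitin ligase MDM2 and the apoptosis genes BAX and FDXR. CDKN1A and MDM2 also passed with the GC and length offset, while BAX and FDXR did not (edgeR adjusted p = 0.0646 and 0.0538). With an effective length offset none of them passed. As a list, mitotic and other cell cycle genes that p53 represses were slightly lower by camera (adjusted p = 5.56e-07; adjusted p = 0.329 with an estimated correlation). Most differences were small, and most of the genes that rose were rich in G and C.

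Of 57 direct p53 target genes in 4 fixed lists, 52 were tested, and 11 rose, 0 fell and 41 did not pass in CASM34. Adjusted over the list alone, 18 rose and 0 fell. The fitted log2 fold change was above 0 for 42 of the 52 and below 0 for 10, with a median of 0.12 and a range from -0.16 to 0.88. Too low to test were TNFRSF10C, TP53AIP1, SPATA18, TRIM22 and CPT1C.

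Among 16 targets for cell cycle arrest and feedback, 3 rose, and adjusted over the list alone 9 rose. CDKN1A (ENSG00000124762.14, GRCh38 chromosome 6, 36676460 to 36687339, plus strand, GENCODE 29), which encodes the cyclin-dependent kinase inhibitor p21, rose from 402 ± 16.8 to 524 ± 9.73 CPM (counts scaled to library size by TMM, SD, n = 2 each), a log2 fold change of 0.38 (SE 0.05, edgeR adjusted p = 0.00274). GADD45A, a growth arrest and DNA damage gene (ENSG00000116717.13, chromosome 1, 67685061 to 67688338, plus strand), rose by 0.29 (SE 0.05, edgeR adjusted p = 0.0128). MDM2 (ENSG00000135679.27, chromosome 12, 68808176 to 68850686, plus strand) rose by 0.23 (SE 0.05, edgeR adjusted p = 0.0255), with fractional counts in all 4 libraries, so its level includes reads shared with other gene models. The phosphatase gene PPM1D had a log2 fold change of 0.09 (SE 0.09, edgeR adjusted p = 0.666), which turned to -0.02 without p53WT replicate 1. As a list these targets were higher in CASM34 by camera with its preset correlation (adjusted p = 2.61e-05), but not with one estimated from the data (adjusted p = 0.329 with an estimated correlation).

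Among 13 tested apoptosis targets, 5 rose, and adjusted over the list alone 6 rose. FDXR, a mitochondrial ferredoxin reductase gene (ENSG00000161513.12, chromosome 17, 74862497 to 74873031, minus strand), rose from 66.4 ± 2.27 to 91.4 ± 2.11 CPM (SD, n = 2 each), a log2 fold change of 0.46 (SE 0.05, edgeR adjusted p = 0.00171). PIDD1, a death domain gene, rose by 0.43, BAX, which encodes a pore-forming protein of the mitochondrial outer membrane (ENSG00000087088.21, chromosome 19, 48954815 to 48961798, plus strand), by 0.34, and TP53I3 by 0.31 (edgeR adjusted p = 0.00921, 0.0109 and 0.0352). The fifth, the nuclease gene AEN, was singled out after its values were seen and rose by 0.21 (SE 0.05, edgeR adjusted p = 0.0392). The BH3-only genes BBC3 (PUMA) and PMAIP1 (NOXA) did not pass, with log2 fold changes of 0.40 (SE 0.11, edgeR adjusted p = 0.0811) and 0.09 (SE 0.06, edgeR adjusted p = 0.478). PMAIP1 lay at 0.04 without p53WT replicate 1 or without CASM34 replicate 2, at 0.14 without either of the others and at 0.15 with the GC and length offset, and passed in none of these. BBC3 passed without CASM34 replicate 1, with a log2 fold change of 0.47 (adjusted p = 0.0277), and with no filter on low counts (adjusted p = 0.0398). It lay at 0.18 with the GC and length offset (edgeR adjusted p = 0.556), and DESeq2 left it at 0.40 (adjusted p = 0.261). The list was higher by camera (adjusted p = 0.000523; adjusted p = 0.329 with an estimated correlation).

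Among 8 DNA repair targets 1 rose, DDB2, a gene for recognition of damaged DNA, by 0.33 (SE 0.07, edgeR adjusted p = 0.0398). The repair list had 4 members above and 4 below 0, and it did not pass camera (adjusted p = 0.885). Among 15 tested targets in metabolism and other functions 2 rose, and adjusted over the list alone 3 rose. GDF15, a secreted stress cytokine gene (ENSG00000130513.7, chromosome 19, 18374731 to 18389176, plus strand), rose from 20.5 ± 1.54 to 30.1 ± 2.69 CPM (SD, n = 2 each), a log2 fold change of 0.55 (SE 0.09, edgeR adjusted p = 0.00976), and the receptor gene NOTCH1 rose by 0.33 (SE 0.07, edgeR adjusted p = 0.0255). This list was higher by camera (adjusted p = 0.00248; adjusted p = 0.329 with an estimated correlation), except without p53WT replicate 2 (adjusted p = 0.0714).

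The number of p53 targets that rose was 2 without p53WT replicate 1, 6 without p53WT replicate 2, 13 without CASM34 replicate 1 and 12 without CASM34 replicate 2. CDKN1A and FDXR passed in all 4 of these fits. With an offset that removed each library's trend on GC content and length, 2 targets passed, CDKN1A at 0.29 (edgeR adjusted p = 0.0207) and MDM2 at 0.28 (edgeR adjusted p = 0.0373), while the median over the 52 targets was 0.15 and FDXR, PIDD1 and NOTCH1 lay at 0.26, 0.16 and 0.10. None of the 52 passed with an effective length offset or in limma on log2(TPM + 1), although most of the named folds were of similar size: CDKN1A lay at 0.38 in both and GADD45A at 0.29 in both (adjusted p = 0.175 and 0.257 with the offset). BAX was larger, at 0.51 in both, and MDM2 smaller, at 0.15 and 0.14.

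**Figure D1:**
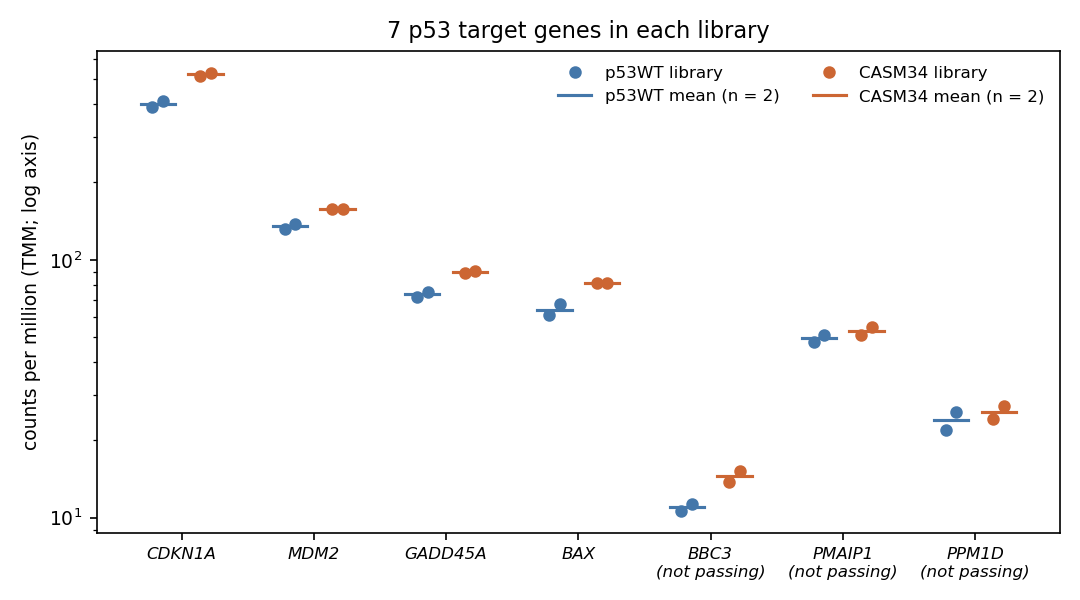
CPM on a log axis of 7 p53 target genes, with a point for each of the 2 p53WT and 2 CASM34 libraries and a line at each group mean. CDKN1A has a mean of 402 CPM in p53WT and 524 CPM in CASM34.

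Few cell cycle genes passed singly. Of 22 cell cycle genes that p53 represses through the DREAM complex, 2 fell, and adjusted over the list alone 15 fell. All 22 fitted log2 fold changes lay below 0, from -0.23 to -0.05. CDK1, the main mitotic kinase gene (ENSG00000170312.17, chromosome 10, 60778331 to 60794852, plus strand), fell from 139 ± 2.56 to 118 ± 5.22 CPM (SD, n = 2 each), a log2 fold change of -0.23 (SE 0.05, edgeR adjusted p = 0.0286). BUB1, a spindle checkpoint kinase gene (ENSG00000169679.15, chromosome 2, 110637698 to 110678114, minus strand), had a log2 fold change of -0.22 (SE 0.05, edgeR adjusted p = 0.0306). CCNB1, TOP2A and AURKA, singled out after their values were seen, lay at -0.16, -0.15 and -0.16 and did not pass (edgeR adjusted p = 0.0787, 0.0932 and 0.0971). The list was lower in CASM34 by camera (adjusted p = 5.56e-07; adjusted p = 0.329 with an estimated correlation) and by fry (adjusted p = 0.0267). Of 20 S phase and E2F genes 1 fell, and adjusted over the list alone 5 fell. Of these 20 genes 18 lay below 0, and the list was lower by camera (adjusted p = 0.00201; adjusted p = 0.491 with an estimated correlation). It did not pass without p53WT replicate 2 (adjusted p = 0.0603) or without CASM34 replicate 2 (adjusted p = 0.0517). Of 20 genes for DNA damage sensing and repair 1 fell, the homologous recombination gene BRCA1, with a log2 fold change of -0.27 (SE 0.06, edgeR adjusted p = 0.0392). Adjusted over the list alone 4 fell, 19 of the 20 lay below 0, and the list was lower by camera (adjusted p = 0.000358; adjusted p = 0.329 with an estimated correlation). With the GC and length offset these 3 lists still passed camera as lower (adjusted p = 1.14e-07, 5.26e-06 and 0.00114), but none of their members passed singly: CDK1 lay at -0.14, BUB1 at -0.17 and BRCA1 at -0.22 (edgeR adjusted p = 0.169, 0.105 and 0.132). BRCA1 lay at -0.10 with an effective length offset and at -0.08 in limma on log2(TPM + 1).

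Of the 15 cholesterol synthesis genes 2 fell, and adjusted over the list alone 4 fell. HMGCS1, which makes the precursor of mevalonate, had a log2 fold change of -0.25 (SE 0.06, edgeR adjusted p = 0.0376). INSIG1, a sterol sensor gene, had one of -0.21 (SE 0.05, edgeR adjusted p = 0.0413). Of these genes 13 lay below 0, and the list was lower by camera (adjusted p = 0.00248; adjusted p = 0.329 with an estimated correlation) and by fry (adjusted p = 0.0267), but not by camera without CASM34 replicate 2 (adjusted p = 0.0517). None of the 12 tested immediate early genes passed singly, although all 12 lay above 0, and adjusted over the list alone JUNB and IER2 rose, by 0.20 and 0.17 (singled out after their values were seen). Both genes turned to -0.03 with the GC and length offset. That list was higher by camera (adjusted p = 0.00248; adjusted p = 0.353 with an estimated correlation), but not with the GC and length offset (adjusted p = 0.245).

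Of 8 further lists, on stress, inflammation, matrix, metabolism and translation, none passed camera, and few of their members changed. ASNS, the asparagine synthetase gene, fell among 18 genes of the unfolded protein and integrated stress response, with a log2 fold change of -0.20 (SE 0.05, edgeR adjusted p = 0.0473) and fractional counts in all 4 libraries. The small chaperone gene HSPB1 rose among 10 heat shock genes, by 0.22 (SE 0.05, edgeR adjusted p = 0.0321), with fractional counts in 2 libraries. ISG15 rose by 0.26 among 17 tested interferon genes, and the heme oxygenase gene HMOX1 by 0.23 among 10 tested NRF2 genes (edgeR adjusted p = 0.0222 and 0.0477). With the GC and length offset none of these 4 genes passed: ASNS lay at -0.16, HSPB1 at 0.05, ISG15 at 0.10 and HMOX1 at 0.11 (edgeR adjusted p = 0.148, 0.615, 0.363 and 0.393). Camera gave these 4 lists adjusted p-values of 0.853, 0.555, 0.660 and 0.555. None of the 9 tested NF-kB genes, 18 tested epithelial-mesenchymal and matrix genes, 16 tested hypoxia and glycolysis genes or 20 ribosomal protein genes passed singly by edgeR. Their lists had camera adjusted p-values from 0.0705 for the matrix genes to 0.211 for the ribosomal protein genes. With the GC and length offset the matrix list passed as higher (adjusted p = 0.0436) and the hypoxia list as lower (adjusted p = 0.0230), and without p53WT replicate 1 the ribosomal protein list passed as lower (adjusted p = 0.0161). On all 4 libraries and without that offset, these 3 lists had adjusted p = 0.353, 0.775 and 0.821 with an estimated correlation.

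**Figure D2:**
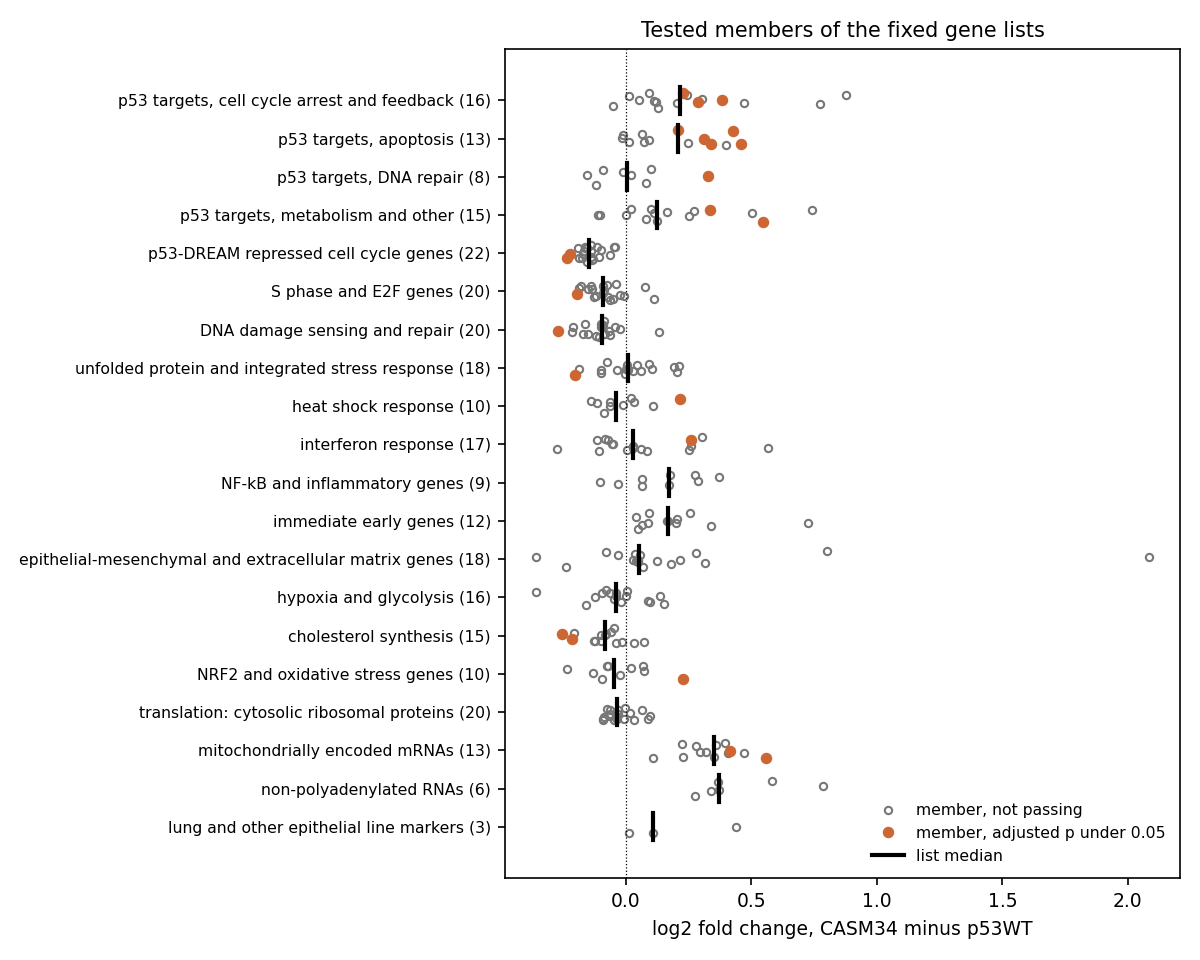
Log2 fold change (CASM34 minus p53WT) of each tested member of 20 fixed gene lists, with filled points for members that passed edgeR and a bar at each list's median. The 22 DREAM genes all lie below 0, from -0.23 to -0.05, and 42 of the 52 tested p53 targets lie above 0.

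Signs of RNA and library quality moved with the groups in part. The 13 mitochondrially encoded mRNAs all lay above 0, with a median log2 fold change of 0.35, and MT-ND2 and MT-ND6 rose, by 0.41 (SE 0.09) and 0.56 (SE 0.13; edgeR adjusted p = 0.0381 and 0.0489), MT-ND2 with fractional counts in 3 libraries. Without p53WT replicate 2 neither passed, at 0.27 and 0.40 (edgeR adjusted p = 0.201 and 0.214), and without CASM34 replicate 1 they lay at 0.27 and 0.26 and passed. Adjusted over the list alone 11 rose, and the list was higher by camera (adjusted p = 0.00248; adjusted p = 0.587 with an estimated correlation). It did not pass without p53WT replicate 2 (adjusted p = 0.306) or without CASM34 replicate 1 (adjusted p = 0.104). Mitochondrially encoded genes took 1.44% and 1.09% of counts in p53WT and 1.81% and 1.45% in CASM34. The list of RNAs taken to lack a poly(A) tail had 6 tested members, the histone genes H1-2, H2AC6, H2BC4 and H4C8 and the RNAs RN7SL1 and RN7SK. Whether their reads came from transcripts with a tail was not tested. All 6 lay above 0 with a median of 0.37, none passed by edgeR, and adjusted over the list alone 3 rose. That list was higher by camera (adjusted p = 0.0176; adjusted p = 0.329 with an estimated correlation). It did not pass without p53WT replicate 1 (adjusted p = 0.0502), p53WT replicate 2 (adjusted p = 0.295) or CASM34 replicate 1 (adjusted p = 0.0682). Its share of counts was 0.00576% and 0.00513% in p53WT and 0.00741% and 0.00702% in CASM34. None of 8 leukocyte markers was high enough to test (at most 0.308 CPM in any library), and of 8 fibroblast and endothelial markers DCN and VWF were tested and did not pass (edgeR adjusted p = 0.716 and 0.811). Of 12 markers of lung and other epithelial lines 3 were tested (KRT8, KRT18 and CLDN4), and none passed by edgeR. Adjusted over the list alone 2 rose, and the list did not pass camera (adjusted p = 0.0875) but did pass fry as higher (adjusted p = 0.0266; adjusted p = 0.389 with an estimated correlation in camera).

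Across 15965 genes tested by edgeR, 312 changed, of which 257 rose and 55 fell. The median absolute log2 fold change of the 312 was 0.32, and 225 of the 257 rises were under 1.5-fold. In 311 of the 312 the groups did not overlap, where chance gives 33.3% of genes and 47.9% of all tested genes had this order. The median GC content of the transcripts was 63.9% for the genes that rose, 42.7% for those that fell and 49.5% for all tested genes. Of 440 genes over 65% GC with a mean above 1 CPM, 96 rose and 0 fell. Across genes, which are not independent replicates, GC content and log2 fold change had a Spearman correlation of 0.53. The slope of a library's log2 level on GC content, per 10 percentage points, was -0.0593 and -0.0493 in p53WT and 0.0707 and 0.0380 in CASM34. With the GC and length offset 31 genes passed, 20 higher and 11 lower, of which 27 were among the 312. The number of genes that changed was 109 without p53WT replicate 1, 153 without p53WT replicate 2, 497 without CASM34 replicate 1 and 919 without CASM34 replicate 2. It was 0 in limma on log2(TPM + 1), where 1820 genes had an unadjusted p under 0.05, and 3 with an effective length offset, where 1901 had one; the edgeR test itself had 2734.

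**Figure D3:**
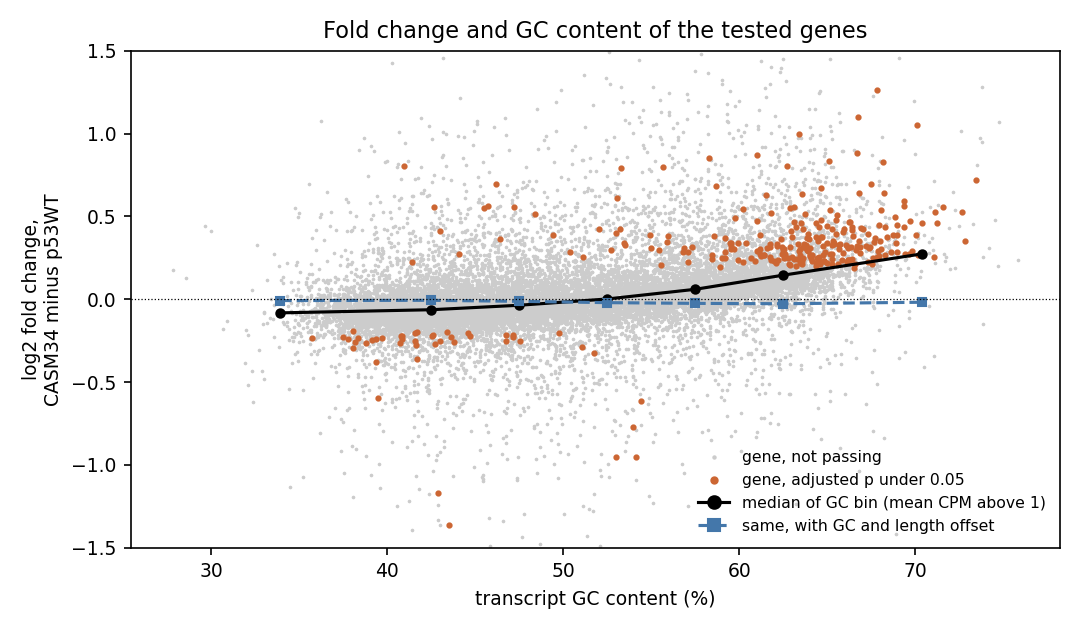
Log2 fold change (CASM34 minus p53WT) of 15597 tested genes against the GC content of their transcripts in percent, with the genes that passed edgeR marked, lines for the median of each GC bin before and after the GC and length offset, and 67 genes beyond ±1.5 not drawn. Genes that rose have a median GC content of 63.9% and those that fell one of 42.7%.

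The 12 named genes with the largest rises had GC contents from 55.2% to 70.1%, and none had a mean above 18.6 CPM in either group. FAM187A (ENSG00000214447.5, chromosome 17, 44899712 to 44905390, plus strand) had 0 counts in both p53WT libraries and 132 and 24 counts in the CASM34 libraries. Fractional counts were present in 2 libraries. Against a floor of 3 counts per library it was at least 22.6-fold higher in CASM34 (edgeR adjusted p = 0.00497). This bound covers counting error only, not the division of reads between gene models, so the level of FAM187A is uncertain. Without CASM34 replicate 1 this bound was 9.51-fold, and without CASM34 replicate 2 it was 35.8-fold. ESPN, which encodes an actin-bundling protein, rose by 1.26, but lay at -0.10 in limma on log2(TPM + 1) and at -0.09 with an effective length offset. The glutamate receptor subunit gene GRIN3B rose by 1.05, but did not pass without p53WT replicate 1 or 2 (edgeR adjusted p = 0.116 and 0.136), and lay at 0.67 with the GC and length offset (edgeR adjusted p = 0.246). The sphingolipid transporter gene SPNS2 rose from 2.41 ± 0.0917 to 4.83 ± 0.163 CPM (SD, n = 2 each), with a log2 fold change of 0.54 under an effective length offset. ARC, a neuronal activity gene, rose from 9.21 ± 1.04 to 17.0 ± 1.28 CPM (SD, n = 2 each), a log2 fold change of 0.88 (SE 0.12, edgeR adjusted p = 0.00425). DPYSL4 rose by 0.81 and the poly(A)-binding protein gene PABPC1L by 0.80 (edgeR adjusted p = 0.00695 and 0.00884). The pseudogenes PKD1P1 and SLC6A10P, the readthrough gene PPT2-EGFL8, the endonuclease subunit gene EME2 and the lysosomal enzyme gene IDUA rose by 0.83 to 1.10. All of these 5 had fractional counts in at least 2 libraries, so their levels are uncertain. EME2 lay at 0.55 without p53WT replicate 2 (edgeR adjusted p = 0.0987), PPT2-EGFL8 at 0.44 with an effective length offset and IDUA at 0.52 with the GC and length offset.

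The 12 named genes with the largest falls included 4 with fractional counts in all 4 libraries, the long noncoding RNA LINC02802 (-1.56), EIF3CL (-0.61), which has the near-identical copy EIF3C, the NF-kB subunit gene REL (-0.60) and TRIM59 (-0.29). The small cytoplasmic RNA BCYRN1 lay at -0.95 (edgeR adjusted p = 0.0430). ESCO2, which encodes a cohesin acetyltransferase (ENSG00000171320.15, chromosome 8, 27771949 to 27812640, plus strand), fell from 30.7 ± 1.64 to 23.7 ± 1.85 CPM (SD, n = 2 each), a log2 fold change of -0.38 (SE 0.08, edgeR adjusted p = 0.0364). PBK, a mitotic kinase gene whose end overlaps that of ESCO2 on the opposite strand, lay at -0.27. The strand setting is not known, but neither gene had fractional counts, so no reads were seen to be shared between them. With an effective length offset LINC02802 lay at -0.38 and ESCO2 at -0.79, and neither passed. On the log2(TPM + 1) scale, which understates changes of low genes, REL lay at -0.28. The DNA primase subunit gene PRIM2 lay at -0.26 and BRCA1 at -0.27, beside ELF2 (-0.36), LRRC42 (-0.29) and HSD17B11 (-0.26). Of the 44 named genes that passed edgeR, 12 passed without p53WT replicate 1, 16 without p53WT replicate 2, 31 without CASM34 replicate 1 and 42 without CASM34 replicate 2. In all 4 of these fits CDKN1A, FDXR, FAM187A, ARC, SLC6A10P, DPYSL4 and PABPC1L passed. With the GC and length offset 5 passed: CDKN1A, MDM2, FAM187A, SLC6A10P and PABPC1L.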

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

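The GC and length offset was chosen only after the results were seen. The number of genes that changed (312, with 257 higher, 55 lower and 11 p53 targets) stayed within 1.5 times under median-of-ratios and upper-quartile scaling, a mean CPM of at least 1, limma-voom and without the mitochondrially encoded genes. Library totals alone gave 27 lower genes and raised the share of higher genes to 88% by less than 10 percentage points, and DESeq2 gave 160 higher genes; it kept 169 of the 285 calls to which it gave an adjusted p. With no filter on low counts, which brings in genes that were too low to test, 777 genes passed (542 higher, 235 lower, 69.8% higher). The added genes are not the whole reason, since genes tested before also had smaller p-values. The edgeR adjusted p of CDKN1A went from 0.00274 to 6.10e-10 and that of FDXR from 0.00171 to 4.67e-12. The stricter 1.5-fold threshold left 3 genes and an adjusted p under 0.01 left 57. In limma on log2(TPM + 1), 0 genes passed (0 higher, 0 lower, 0 p53 targets), and ESPN lay at -0.10. The effective length offset gave 3 genes (3 higher, 0 lower, 0 p53 targets), with ESPN at -0.090. The cause was not tested for DESeq2, the TPM scale or the effective length offset. With the GC and length offset 31 genes passed (20 higher, 11 lower, 2 p53 targets), and the list of the unfolded protein response turned from higher to lower, without passing in either (adjusted p = 0.612).

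Leaving out each library in turn leaves a group with 1 library, which is assumed to vary like the other group. It gave 109 to 919 genes, 95 to 650 higher, 14 to 269 lower, and 2 to 13 p53 targets. PPM1D, which never passed, ranged from -0.016 to 0.22, and 6 to 10 lists passed. The adjusted p of the p53 metabolism list ran from 0.00362 to 0.0714. Lists that changed sides were DNA repair targets (0.795 to 0.986), the unfolded protein response (0.571 to 0.982) and ribosomal proteins (0.0161 to 0.887, with the lowest value on the original side). With an estimated correlation 0 of the 20 lists passed in camera. The p53 arrest, apoptosis and metabolism lists and the DREAM list had an adjusted p of 0.329 in that test. Their estimated correlations were 0.0931, 0.0750, 0.00121 and -0.0207. The metabolism and DREAM lists thus lay below the preset 0.01, so a higher correlation is not why these lists did not pass. The 10 simulated shifted lists did not pass with an estimated correlation either. Those simulated genes were independent, so this does not show that the preset correlation is right for the real lists. With fry 3 lists passed, and the 3 p53 lists had 0.0922.

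For the 47 named genes, 742 values under the alternatives comprised 499 on the same side of the threshold, 237 that no longer passed, 3 that newly passed (all BBC3: with no filter, with the replicate block and without CASM34 replicate 1) and 3 of opposite sign (ESPN on the TPM scale and with the effective length offset, and PPM1D without p53WT replicate 1). With a replicate block 1159 genes passed (798 higher, 361 lower, 18 p53 targets), among them all 312. The labels do not say that equal numbers mark a pair, so the block has no support in the labels. Across genes, the replicate 1 deviations from the group mean had a correlation of 0.0335 between the groups. With 2 libraries per group the replicate 2 deviations mirror these and add nothing, so this value cannot settle whether libraries were paired. The mitochondrial share of counts was higher in replicate 1 than in replicate 2 of both groups (1.44% and 1.09% in p53WT, 1.81% and 1.45% in CASM34). At these depths and with 2 libraries per group, the test recovered 70% of simulated 1.5-fold changes and 40% of the smallest ones simulated.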

Other observations

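The tests of GC content and length were chosen only after the results were seen. The genes in this paragraph and the next were singled out after their values were seen. Beyond the named genes, PLTP, which encodes a phospholipid transfer protein, rose by 0.49 on the log2 scale (edgeR adjusted p = 0.000686), and CYFIP2, a gene known to be induced by p53, rose by 0.43 (edgeR adjusted p = 0.00264). Both also passed with the GC and length offset, at 0.38 and 0.39 (edgeR adjusted p = 0.00218 and 0.00949). So did the retinol dehydrogenase gene RDH10 (0.37 without and 0.39 with the offset) and CITED2, a transcriptional coregulator gene (0.28 with and without it). RACGAP1, needed for cytokinesis, had a log2 fold change of -0.25 (edgeR adjusted p = 0.0150) and -0.22 with the offset (edgeR adjusted p = 0.0407). SCD, the stearoyl-CoA desaturase gene, had one of -0.23 (edgeR adjusted p = 0.0247) and -0.21 with the offset (edgeR adjusted p = 0.0382). Only with the offset did 4 further genes pass, H2AJ (0.30), MT-ND3 (0.41), DYNC2I2 (-0.21) and the fatty acid synthase gene FASN (-0.28), which had lain at 0.23, 0.22, 0.05 and -0.01 without it.

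Several p53 targets had sizeable log2 fold changes without passing in edgeR: SFN at 0.88 (adjusted p = 0.0997), BTG2 at 0.47 (adjusted p = 0.0660) and PLK3 at 0.30 (adjusted p = 0.0779). They lay at 0.71, 0.46 and 0.19 with the GC and length offset (edgeR adjusted p = 0.282, 0.142 and 0.372).

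More genes rose than fell, and those that rose were rich in G and C. The choice among the scalings tried is argued against, since over 3 other scalings the share of higher genes was at least 81.2%. Those scalings lay close together, with a median log2 fold change of all tested genes from -0.00295 to 0.00357. The test was therefore weak. The GC and length offset ended 239 of the 257 rises and 46 of the 55 falls. The fold shrank in 228 of these 239 (median log2 fold change 0.32 to 0.12, median SE 0.0595 to 0.0532) and, by less, in 41 of these 46 (-0.25 to -0.19, median SE 0.0521 to 0.0465), while it did not shrink in 11 and 5. With fewer genes passing, the largest unadjusted p that passed edgeR also went from 0.000967 to 9.35e-05, which ended calls such as LRRC42 with a kept fold (-0.29 before and after). A trend of the libraries on GC content, from RNA quality or library preparation, is a candidate cause. The excess in number went mostly with the trend: 257 genes were higher and 55 lower without the offset, and 20 and 11 with it. As a share, 64.5% of the 31 genes that passed with the offset were higher (exact 95% interval over genes, taken as independent, 45.4% to 80.8%). This share does not settle whether an excess of rises remains. The trend and the group cannot be told apart, because the slope differed by 0.109 between the groups and by -0.01 and 0.0327 within them, and a biological rise of GC-rich genes would give the same slope. With 4 libraries there are 3 splits into 2 against 2, too few for a share under 0.05: 1 of the 3, the real one, gave 312 genes and the highest other gave 5.

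As lists, p53 targets for arrest, apoptosis and metabolism were higher in CASM34 by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.329) or by fry (adjusted p = 0.0922). GC content and expression of the targets are argued against as the whole cause, because the targets' median of 0.12 lay at percentile 100 of 10000 random lists matched on both, whose central 95% ran from -0.05 to 0.02. The targets had a median GC content of 48.1%, against 49.5% for all tested genes, so their median fold had little to lose to the offset. That 121% of it was left (bootstrap over genes, taken as independent, 69.7% to 145%) is therefore weak evidence against the GC and length trend as its cause. It says nothing of the single target calls, 11 without and 2 with the offset. Of the targets named by the rule that rose, MDM2 had a GC content of 41.4%. The others ran from 53.5% (DDB2) to 66.0% (PIDD1), above the median of all tested genes. Single calls shrank, FDXR from 0.46 (SE 0.05) to 0.26 (SE 0.05, edgeR adjusted p = 0.0538), while MDM2 went from 0.23 to 0.28. A biological difference between CASM34 and p53WT stays open and untested. So does a difference in culture, RNA quality or library preparation that moves with the groups. The lists of mitochondrially encoded mRNAs and of RNAs taken to lack a poly(A) tail were higher too and passed camera with the offset (adjusted p = 2.06e-05 and 0.00272). Without the offset these lists had adjusted p = 0.587 and 0.329 with an estimated correlation, and camera did not pass them without p53WT replicate 2 (adjusted p = 0.306 and 0.295) or without CASM34 replicate 1 (adjusted p = 0.104 and 0.0682).

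Of the 24 genes that changed 2-fold or more, 12 were higher and 12 lower, 9 had 0 counts in both libraries of 1 group, and 13 have no symbol. Fractional counts are a sign of reads shared between gene models. They were present in 95.8% of the 24 and in 36.9% of 1090 genes of similar expression (Fisher's exact test over genes, taken as independent, two-sided p = 2.52e-09). This fits shared reads being divided differently between overlapping or similar gene models, which may explain most of the largest fold changes, CHURC1-FNTB and CORO7-PAM16 among them. No biological explanation was tested for these genes.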
